A study of Mus musculus with 8 samples.

How the data were processed

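Droplet-based single-cell RNA sequencing was done on mouse liver spheroids grown from 2 cell lines, Hepa 1-6, a hepatoma line, and KUP5, a Kupffer cell (liver macrophage) line. Spheroids were left untreated or exposed for 6 h to 6.25 µg/mL of 1 of 3 particles: V2O5 (vanadium pentoxide, a metal oxide), GO (graphene oxide, a carbon sheet) or TiO2 (titanium dioxide, a metal oxide). Each of the 4 groups had 2 libraries, 8 in all. Per the submitters' processing notes, libraries were made with version 3.1 of the 10x Genomics 3′ chemistry, and reads were aligned and counted with Cell Ranger 3.0.2 on the mm10 build. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers with no normalisation, and each gene is given with an Ensembl identifier. The annotation release used for counting and the way barcodes were called as cells are not given in the sources. Of 31053 gene identifiers, 30934 (99.6%) were found in GENCODE M21 on GRCm38, which gave the coordinates printed below.

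Libraries held 4777 to 10830 barcodes and 67844284 to 124457333 UMIs. Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, in all 45062 of 54842. Scrublet, run per library through scanpy 1.11.5, called only 6 of them (0.013%) as doublets, so doublet removal did not work here, and the 45056 cells that went on include doublets. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 0.5) gave 9 clusters, with no batch integration. Clusters were named from marker lists for hepatocytes, Kupffer cells or macrophages, stellate cells, endothelial cells, cholangiocytes, T or NK cells, B cells, neutrophils and erythroid cells, but the thresholds were set after the clusters had been seen. A cluster was called macrophage-like with at least 5000 CPM (UMIs per 1000000 UMIs) of macrophage markers and at most 1000 CPM of Krt8 plus Krt18. It was called Krt8/Krt18-high with at least 1500 CPM of these keratins, at most 2000 CPM of macrophage markers and a median UMI count of at least 0.5 times that of its libraries. Cells of the other clusters stayed unnamed and entered no class. A cell's nearest cluster centre gave the same class for 96.6% of cells. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only, and treated and control libraries were compared with a two-sided exact permutation test, whose smallest possible p is 0.33 with 2 libraries against 2.

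UMI counts were summed per library and class and tested with edgeR 4.0.16, using its quasi-likelihood test with robust estimation, TMM normalisation and genes kept by filterByExpr. All 8 libraries of a class were fitted together by group, with 4 residual degrees of freedom, and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 3 particles were each compared with control and with each other in both classes, and class interactions were tested on 16 summed profiles with library as a block. CPM values are means ± SD over 2 libraries, and fold changes are log2 values with the SE of the fit. The labels do not say whether the 2 libraries of a group came from separate cultures, so p values measured only the spread between libraries. Libraries of 1 replicate number correlated across groups (12 of 12 per class above 0.1, from 0.33 to 0.9), so the numbers pair. A fit with replicate number as an added term (3 residual degrees of freedom; in the class interactions, replicate number by class) was fixed as an alternative from the start and is called the blocked test. In 3 self-tests (200 simulated changes) the unblocked test recovered 0% of 1.5-fold, 5.1% of 2-fold and 44.4% of 4-fold changes in Krt8/Krt18-high cells. The blocked test recovered 36%, 74.1% and 84.2%. In macrophage-like cells the shares were 0%, 6% and 54.1% unblocked and 26.8%, 62.2% and 84.7% blocked. Of unchanged genes the blocked test called 47 of 43121 in the first class and 54 of 36387 in the second, 11% and 13.6% of its calls, and in the interaction 26 of 23526 (13.9%). The unblocked test called 0, 1 and 1. The blocked shares exceed 0.05 and depend on how many genes were changed.

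Before the data were examined, 23 gene lists were fixed: NRF2 and antioxidant genes; metallothionein, zinc and iron handling; NF-kB cytokines and chemokines; inflammasome and pyroptosis; p53 targets; apoptosis machinery; integrated stress response; endoplasmic reticulum unfolded protein response; heat shock and proteostasis, immediate early genes, interferon response, AhR and xenobiotic metabolism, cholesterol biosynthesis and uptake, fatty acid and lipid droplet genes, glycolysis, hypoxia response, lysosome and autophagy, scavenger receptors and phagocytosis, mitochondrially encoded transcripts, nuclear-encoded respiratory chain, S phase genes, G2 and M phase genes, and collagen and matrix remodelling. The tests, the alternatives not said to be added and the rule for named genes were fixed at the same time. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 23 lists, then with an estimated correlation and with fry. A simulated list (23 genes shifted 1.25-fold) was found in 3 of 3 self-tests in each class and fit. They did not test correlation within lists. Of 66 unshifted lists 2 were called in macrophage-like cells with the block, 1 in Krt8/Krt18-high cells without it, and 0 in the other 2 cases.

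Genes were named by rule. Part 1 took the 6 largest rises and 6 largest falls (5 each way between particles and for class interactions) with an adjusted p under 0.05, both treated libraries beyond both controls, a mean of at least 20 CPM and at least 0.1 times the mean in the other class, and left out predicted, ribosomal protein and mitochondrial genes. Part 2 took the 2 members with the smallest p of each list with 3 or more called members. Part 3 took Hmox1, Mt1, Mt2, Il1b, Tnf, Cxcl2, Nlrp3, Gdf15, Cdkn1a and Ddit3, up to 30 genes per comparison. Parts 1 and 2 named no gene in the unblocked test, so a changed rule was applied to the blocked test, a choice made after the data were seen. In it each treated library had to lie on the same side of the control of its own replicate number, in place of beyond both controls. Named genes such as Stc1, Hist1h4i and H2-Q1 would not have met the first form. List members given as examples were picked after their values were seen.

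Alternatives fixed with the lists were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, the replicate block, only the 4 libraries compared, leaving out each library, doublet calls kept, no barcode filter, a stricter filter (1000 genes, 10% mitochondrial), each library clustered by itself, profiles thinned to the smallest library, glmTreat against a fold of 1.2, all cells summed, and genes far higher in the other class left out. Added after seeing the data were the removal of cells with the highest doublet scores (0.8% per 1000 barcodes), the removal of cells with over 20% of the other class's median marker share, a shallow cluster counted as Krt8/Krt18-high, each setting together with the replicate block, 4 clusters tested one by one, list tests without genes far higher in the other class, and the effect of the replicate number itself. Leaving out 1 library leaves its group with a single replicate number, so unblocked values without a library also hold the difference between replicate numbers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used. No reads or sequences were used, so GC content, read mapping and splicing were not analysed.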

Results

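Single-cell transcriptomes came from 8 libraries of mouse liver spheroids of Hepa 1-6 and KUP5 cells, 2 each for control, V2O5, TiO2 and GO. Control libraries held 6222 and 6298 barcodes with 106751779 and 102614200 UMIs, and V2O5 libraries held 7854 and 10830 barcodes with 67844284 and 123360428 UMIs. TiO2 libraries held 6340 and 7349 barcodes with 100439114 and 121434846 UMIs, and GO libraries 5172 and 4777 barcodes with 124457333 and 112630551 UMIs. The median UMI count per barcode was 16712.5 and 15402 in control, 8362.5 and 10282 with V2O5, 3596 and 15496 with TiO2, and 23319 and 22172 with GO. Barcodes that failed the filters made up 17.4% and 24.2% in control, 21.1% and 12.2% with V2O5, 22.4% and 16.2% with TiO2, and 14.5% and 17.3% with GO. The 10 most abundant genes held 8.4% to 9.9% of the UMIs of a library.

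The 45056 cells fell into 35892 Krt8/Krt18-high cells, 5067 macrophage-like cells and 4097 unnamed cells. Macrophage-like cells expressed 18 of 21 macrophage markers at 10 CPM or more, among them Lyz2 (lysozyme) at 12293 ± 3756 CPM, whereas the Kupffer-restricted Clec4f, Vsig4 and Timd4 were near 0. The other class expressed Krt8 at 1115 ± 153 CPM and Krt18, its partner keratin, at 1789 ± 282 CPM (SD, n = 8 libraries). It expressed only 6 of 20 hepatocyte markers at 10 CPM or more, with albumin (Alb) at 77.9 CPM, and 12 of them were under 1 CPM. It also carried cholangiocyte markers (4 of 8 at 10 CPM or more) such as Krt7 at 120.4 CPM, and 2 of 10 stellate cell markers, with Dcn at 2286 CPM. For endothelial, T or NK, B cell, neutrophil and erythroid markers the number at 10 CPM or more was 0 in this class. It is therefore described as a set of cells defined by 2 keratin transcripts, not as a cell type. Lyz2 stood at 130.6 CPM in it, and free RNA, doublets left in and the cells' own Lyz2 were not told apart.

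Replicate number, more than treatment, ordered the Krt8/Krt18-high cells. Cluster 2, whose leading transcripts included the chemokine Cxcl1 and the cytokine Csf2, held 2646 cells of control replicate 1 and 50 of control replicate 2. Cluster 4, led by the cholangiocyte marker Krt7 at 2-fold its level in other cells, held 264 and 1625 cells of the same libraries. Cluster 6, led by the proliferation genes Mki67 and Top2a, held 87 and 1223, and cluster 5, led by Ctgf and Angpt1, held 66 and 799. Cluster 3, led by Sprr2e and Sprr2j-ps, held 837 and 9. With V2O5, TiO2 and GO too, clusters 2 and 3 together held most cells of replicate 1, and clusters 4, 5 and 6 together most cells of replicate 2. The split between clusters 2 and 3 differed by group: cluster 3 held 75.3% of these cells in V2O5 replicate 1, 44.67% in TiO2 replicate 1 and 41.32% in GO replicate 1. Some results are also given for clusters 2, 4, 5 and 6. Cluster 3, under 20 cells in some libraries, was not tested.

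The share of macrophage-like cells was compared first. They made up 14.24 ± 0.23% of cells in control (SD, n = 2), 8.44 ± 1.61% with V2O5, 7.56 ± 2.88% with GO and 15.89 ± 10.11% with TiO2. Control libraries gave 14.4% (95% Clopper-Pearson interval 13.45 to 15.39) and 14.07% (13.09 to 15.09). V2O5 gave 7.3% (6.66 to 7.97) and 9.57% (8.99 to 10.18), and GO gave 5.52% (4.86 to 6.23) and 9.6% (8.7 to 10.56). Each of these 4 libraries lay below both controls, but not with each library clustered by itself, where control replicate 1 (9.52%) lay below V2O5 replicate 2 (9.9%) and GO replicate 2 (9.57%). TiO2 replicate 1 gave 23.04% (21.87 to 24.25) and replicate 2 gave 8.74% (8.04 to 9.47). The differences from control were -5.8 points for V2O5, -6.68 for GO and 1.66 for TiO2, with two-sided exact permutation p of 0.33, 0.33 and 1 (adjusted 0.5, 0.5 and 1 over 3 tests). The smallest p this exact test allows is 0.33. Unnamed cells made up 8.96 ± 1.04% in control, 2.94 ± 1.52% with V2O5, 23.06 ± 27.68% with TiO2 and 5.56 ± 1.48% with GO. Among named cells alone the V2O5 difference was -6.96 points. The V2O5 difference was -4 points with no barcode filter and -2.83 points with each library clustered by itself, and the GO difference -4.09 and -3.92. Without TiO2 replicate 1 the TiO2 difference was -5.49 points, and without replicate 2 it was 8.8.

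**Figure D1:**
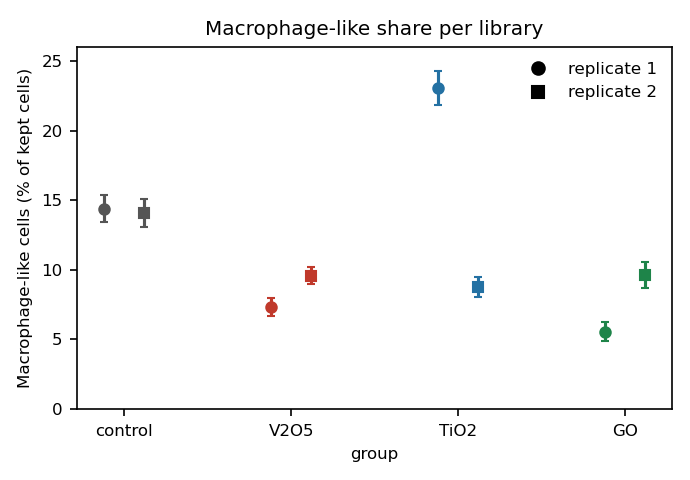
Share of macrophage-like cells among all kept cells (percent, y axis) in each library, by group (x axis); points are libraries with 95% Clopper-Pearson intervals. Both V2O5 libraries (7.3 and 9.57) and both GO libraries (5.52 and 9.6) lie below the controls (14.4 and 14.07), and the TiO2 libraries lie on either side (23.04 and 8.74).

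The comparison of V2O5 with control asked which transcripts a vanadium oxide changes within 6 h. In Krt8/Krt18-high cells Stc1, which encodes the secreted glycoprotein stanniocalcin 1, averaged 69.1 ± 54.5 CPM (SD, n = 2) with V2O5 and 26.6 ± 21.3 CPM in control. Its log2 difference was 1.35 and 1.33 within the 2 replicate numbers. Txnip, an inhibitor of thioredoxin that also limits glucose uptake, averaged 21 ± 1.6 CPM against 63.5 ± 22.7 CPM, with differences of -1.8 and -1.21. In the unblocked edgeR quasi-likelihood test 0 of 14743 genes passed (Stc1 adjusted p = 0.975, Txnip 0.968), with 695 at an unadjusted p under 0.05, 10 genes in DESeq2 and 0 in limma-voom. The blocked edgeR test called 9 genes, 5 up and 4 down, and in 3 self-tests of this class 47 unchanged genes. By the rule within replicate numbers it named Stc1 (ENSMUSG00000014813, chromosome 14, 69029238 to 69041804, GRCm38), which rose by a log2 of 1.39 ± 0.09 SE (adjusted p = 0.00353), although V2O5 replicate 2 (30.5) lay below control replicate 1 (41.7 CPM). It also named 3 genes that fell, Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883; -1.55 ± 0.15, 0.0169) and the histone genes Hist3h2a (-1.44 ± 0.15, 0.0258) and Hist1h4i (-1.14 ± 0.12, 0.0258). Histone genes have near-identical copies, so their reads are hard to assign. The other called genes, named after their values were seen, were Ifi202b, Ptk6, Sprr2h and Lsmem1, which rose, and Arrdc3, which fell. The blocked count of 9 moved to 0 and 32 without control replicates 1 and 2 and to 2314 without V2O5 replicate 2. It was 17 and 16 without GO replicates 1 and 2, 3 without either TiO2 library, and 0 with only the 4 libraries compared.

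Among the fixed lists, G2 and M phase genes fell with V2O5, 49 of 53 lower (median log2 -0.32, camera adjusted p = 7.66e-11, adjusted p = 0.889 with an estimated correlation). Examples are the proliferation marker Mki67 (-0.49 ± 0.18) and the spindle motor Kif11 (-0.56 ± 0.24). Clusters did not share this direction. In camera the list fell in cluster 6 (0.000256), did not pass in cluster 2 (0.0538) or cluster 4 (0.894), and rose in cluster 5 (3e-07). Levels of mitochondrially encoded transcripts rose, 12 of 13 higher (0.38, adjusted p = 8.49e-07, adjusted p = 0.831 with an estimated correlation), led by mt-Nd4l (0.85 ± 0.24) and mt-Nd5 (0.77 ± 0.22), subunits of complex I. The list also rose in clusters 2, 4, 5 and 6 (0.00801, 0.000776, 4.49e-08 and 7.52e-05). Glycolysis genes rose, 16 of 17 higher (0.26, adjusted p = 0.00304, adjusted p = 0.831 with an estimated correlation), with hexokinase 2 (Hk2, 1.3 ± 0.69) and phosphoglycerate kinase (Pgk1, 0.55 ± 0.25) as examples. Hypoxia response genes rose, 18 of 19 higher (0.35, adjusted p = 0.00517, adjusted p = 0.957 with an estimated correlation), with Adm, the vasodilator peptide adrenomedullin, at 1.42 ± 1.01. Unblocked, the glycolysis and hypoxia calls were lost without control replicate 2 or V2O5 replicate 1. With the block glycolysis held, and hypoxia was lost without control replicate 1. The number of called lists was 4, and 7 and 9 without control replicates 1 and 2. The replicate block added falls of p53 targets (adjusted p = 0.121, blocked 0.00879) and immediate early genes (0.0838, blocked 0.00397), both lost in the blocked fit (adjusted p = 0.775 and adjusted p = 0.647 with an estimated correlation). The 19 lists not called, among them NRF2 and antioxidant genes (0.213) and metallothionein genes (0.998), ranged from 0.0838 to 0.998. Adjusted over the list alone, 1 gene passed, Txnip.

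Stress markers named in advance did not pass in these cells (edgeR adjusted p from 0.968 to 0.993, lowest blocked adjusted p 0.127, for Mt2). The metallothionein Mt2 averaged 215.5 ± 245.8 CPM with V2O5 and 91.1 ± 86.4 in control, and Mt1 1267.1 ± 1301.5 and 782.2 ± 709.9. The heme oxygenase Hmox1 averaged 67.2 ± 28.4 and 59.9 ± 11.9, the stress cytokine Gdf15 223.5 ± 27.4 and 368.8 ± 14.1, and Ddit3, a transcription factor of the integrated stress response, 258.2 ± 197.7 and 414.3 ± 272.8. For Cxcl2, a neutrophil chemokine, the levels were 341.9 ± 318.3 and 437 ± 423.5, and for the cell cycle inhibitor Cdkn1a 598.2 ± 46.5 and 620 ± 139.3. Il1b (9.6 ± 10.6 and 5.3 ± 1.6), Tnf (1.5 ± 0.7 and 2.9 ± 1.9) and Nlrp3 (2 and 2.8 CPM) were near the floor. Median UMIs per Krt8/Krt18-high cell were 9635 and 10815.5 with V2O5 against 20229.5 and 19564 in control.

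Within single clusters the blocked test called 143 genes (60 up, 83 down) in cluster 2, 175 (79 up, 96 down) in cluster 4, 1 in cluster 5 and 44 (17 up, 27 down) in cluster 6. Unblocked edgeR calls were 5, 0, 0 and 0, with 400, 480, 166 and 226 genes at an unadjusted p under 0.05. In 3 of the clusters 6 genes rose and 5 fell with V2O5. Risers were Stc1 (0.76 ± 0.2, 1.14 ± 0.18 and 0.82 ± 0.2 in clusters 2, 4 and 6; adjusted p = 0.0226, 0.00167 and 0.0143), the drug efflux pump Abcb1b (0.77, 0.8 and 0.72; 0.0161, 0.00404 and 0.0284), Abcb9, Eif3j1, Lsmem1 and mt-Nd4l. Fallers were the antioxidant quinone reductase Nqo1 (-1.01 ± 0.22, -0.56 ± 0.14 and -0.7 ± 0.18; 0.00174, 0.039 and 0.0402), complement C3 (-0.85 ± 0.16, -0.83 ± 0.11 and -0.73 ± 0.14; 0.000377, 9.94e-05 and 0.00075), Cox20, Nadk2 and Rgs3. Clusters share libraries and so are not independent, and some libraries had as few as 29, 98, 23 and 33 cells in clusters 2, 4, 5 and 6.

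In macrophage-like cells Mmp12, macrophage elastase, averaged 74.5 ± 32 CPM with V2O5 and 31.1 ± 6.8 CPM in control (SD, n = 2), with log2 differences of 1.41 and 0.96 within the replicate numbers. The interferon-induced chemokine Cxcl10 averaged 147 ± 60.5 against 336.6 ± 153.5 CPM, and the pattern receptor Clec4e 144.1 ± 19.7 against 271.6 ± 91 CPM. Tnf, a central inflammatory cytokine, averaged 72.5 ± 10.6 against 131.3 ± 33.2 CPM and did not pass in either test (blocked adjusted p = 0.0934). The unblocked edgeR test called 0 of 12502 genes, with 407 at an unadjusted p under 0.05, 7 genes in DESeq2 and 0 in limma-voom. The blocked edgeR test called 12, of which 4 rose and 8 fell, and in 3 self-tests of this class 54 unchanged genes. By rule it named Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), which rose by a log2 of 1.2 ± 0.15 SE (adjusted p = 0.0216), and Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), which fell by 1.17 ± 0.15 (0.0222). It also named 4 further falls, of the fatty acid carrier Fabp3 (-1.33 ± 0.16, 0.0216), the transcription factor Klf2 (-0.96 ± 0.14, 0.0283), Clec4e (-0.88 ± 0.13, 0.0338) and the protease cathepsin K (Ctsk, -0.79 ± 0.11, 0.0222). The count of 12 ran from 4 to 197 with 1 library left out. It was 60 with no barcode filter, and 0 with only the 4 libraries compared. Cells with markers of both classes made up 36.2% and 12.2% of this class in control and 15.5% and 25.6% with V2O5, and without them the count was 79.

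Of the lists in macrophage-like cells, mitochondrially encoded transcripts rose with V2O5, 13 of 13 higher (median log2 0.35, camera adjusted p = 1.14e-09, adjusted p = 0.648 with an estimated correlation). The median mitochondrial share of UMIs in these cells was 4.09 ± 0.1% with V2O5 and 3.24 ± 0.08% in control. Collagen and matrix remodelling genes rose, 17 of 22 higher (0.34, adjusted p = 0.00258, adjusted p = 0.965 with an estimated correlation), but not without control replicate 2 (0.187) or V2O5 replicate 2 (0.917). The number of called lists was 2, and 5 without control replicate 2, 8 without V2O5 replicate 1 and 1 without V2O5 replicate 2. With the replicate block it was 6. The block added falls of NRF2 and antioxidant genes (adjusted p = 0.376, blocked 0.0407), NF-kB cytokines and chemokines (0.149, blocked 0.0163), p53 targets (0.149, blocked 0.00552), and lysosome and autophagy genes (0.149, blocked 0.0303). All 4 were lost in the blocked fit (adjusted p = 0.748 with an estimated correlation), and the NRF2 (blocked 0.0553) and lysosome (blocked 0.0523) calls also without cells with markers of both classes. The other 21 lists ranged from 0.149 to 0.997. Adjusted over the list alone, 5 genes passed: the granulocyte growth factor Csf3 (1.26), mt-Nd4l (1.08), mt-Nd5 (0.9) and mt-Atp8 (0.88), which rose, and Tnf (-0.85), which fell. Genes named in advance had an unblocked adjusted p of 1, with Hmox1 at 697.3 ± 51.3 CPM against 944.2 ± 156 in control, Gdf15 at 731.9 ± 231.9 against 1092.4 ± 50 and Il1b at 704.1 ± 522.1 against 489.1 ± 339.3. Mt1 (2261.7 ± 1125.1 against 2592.1 ± 1109.3), Mt2 (485.1 ± 265.7 against 496.5 ± 234.6), Cxcl2 (957 ± 383.8 against 863.6 ± 391.1), Cdkn1a (397.9 ± 37.8 against 362 ± 98.2), Ddit3 (103.9 ± 44 against 175.1 ± 113.3) and Nlrp3 (43.7 ± 19.6 against 56.5 ± 30.5) were the others.

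**Figure D2:**
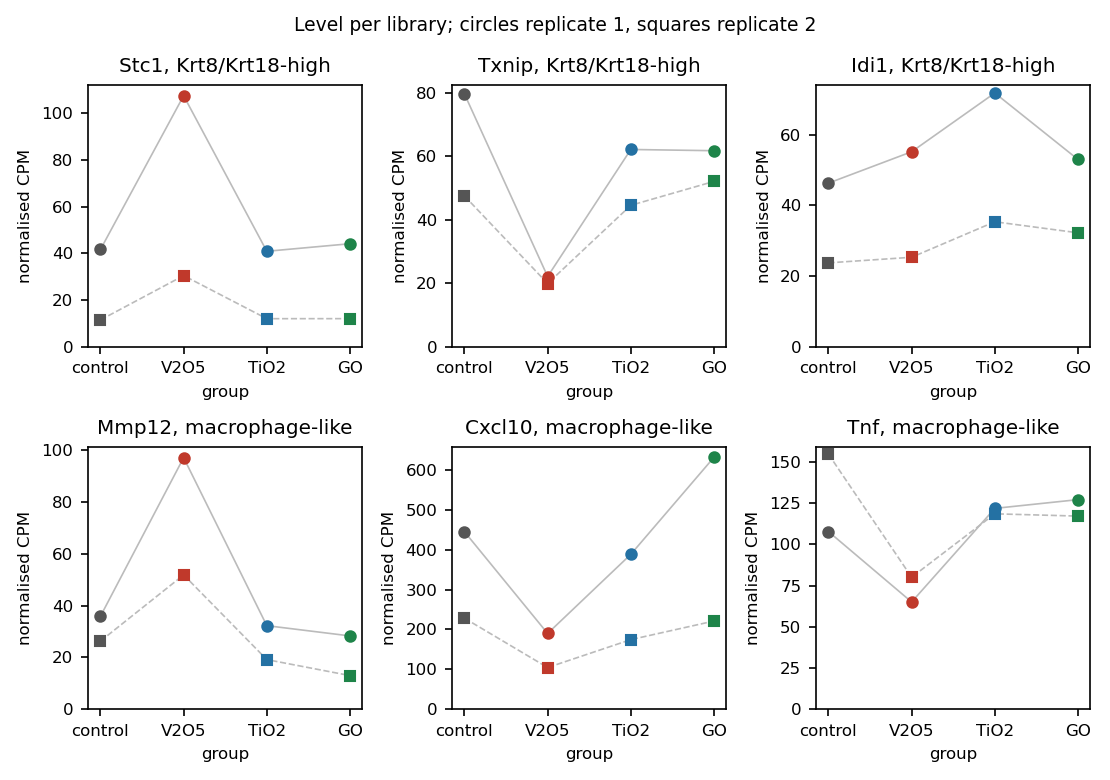
Normalised CPM (y axes) of Stc1, Txnip and Idi1 in Krt8/Krt18-high cells and of Mmp12, Cxcl10 and Tnf in macrophage-like cells, by group (x axes); circles are replicate 1 and squares are replicate 2. Stc1 is higher and Txnip lower with V2O5 than in control within each replicate number.

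The comparison of TiO2 with control asked the same of a poorly soluble oxide. In Krt8/Krt18-high cells cholesterol biosynthesis and uptake genes rose together, with 23 of 23 higher (median log2 0.32, camera adjusted p = 9.2e-13, adjusted p = 0.261 with an estimated correlation), and the call held without each of the 8 libraries. Examples are the isomerase Idi1 (0.61 ± 0.54 SE) and squalene epoxidase (Sqle, 0.47 ± 0.13). The list also rose in clusters 4, 5 and 6 (0.000302, 0.00011 and 0.000233) but not in cluster 2 (0.472). Levels of mitochondrially encoded transcripts rose, 13 of 13 higher (0.28, adjusted p = 3.06e-08, adjusted p = 0.373 with an estimated correlation), unless TiO2 replicate 2 was left out (0.46). NF-kB cytokines and chemokines fell, 32 of 37 lower (-0.35, adjusted p = 4.29e-06, adjusted p = 0.66 with an estimated correlation), with the prostaglandin synthase Ptgs2 at -0.85 ± 0.28. Interferon response genes fell, 27 of 27 lower (-0.25, adjusted p = 0.000163, adjusted p = 0.66 with an estimated correlation), with the antiviral gene Ifit3 at -0.86 ± 0.58. The NF-kB call was lost without control replicate 1 (0.275), without TiO2 replicate 2 (0.753) and without genes far higher in macrophage-like cells (0.075, blocked 1.79e-06). With the block it held without each of the 8 libraries. The interferon call was lost without control replicate 2 (0.323) or TiO2 replicate 1 (0.123).

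Immediate early genes fell with TiO2, 21 of 26 lower (adjusted p = 0.00117, adjusted p = 0.831 with an estimated correlation), with the transcription factor Fos at -0.64 ± 0.21. The call was lost without control replicate 1 (0.595) or TiO2 replicate 2 (0.573). S phase genes rose, 35 of 41 higher (adjusted p = 0.000394, adjusted p = 0.734 with an estimated correlation), but not without control replicate 2 (0.604) or TiO2 replicate 1 (0.15). They fell in cluster 2 (0.00328) and rose in clusters 4 and 5. Weaker falls were called for NRF2 and antioxidant genes (0.0187, adjusted p = 0.373 with an estimated correlation), lysosome and autophagy genes (0.0187, adjusted p = 0.546 with an estimated correlation) and hypoxia response genes (0.0407, adjusted p = 0.907 with an estimated correlation). The NRF2 call was lost unblocked without any 1 control or TiO2 library but held with the block. It was lost without genes far higher in macrophage-like cells (0.121, blocked 0.0657). The lysosome call was lost unblocked without either control library or TiO2 replicate 2, and hypoxia without control replicate 1 or TiO2 replicate 2. With the replicate block fatty acid and lipid droplet genes (adjusted p = 0.0759, blocked 0.0476) also rose and scavenger receptor genes (0.0541, blocked 0.0227) also fell, both lost in the blocked fit (adjusted p = 0.59 with an estimated correlation). The lipid call was lost without cells with markers of both classes (blocked 0.0518). The scavenger receptor call was lost without genes far higher in macrophage-like cells (blocked 0.721 for 8 genes). The 14 lists not called ranged from 0.0541 to 0.958. No single gene passed: edgeR called 0 of 14743 with and without the block and 0 adjusted over the list alone. There were 68 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. Within clusters 2, 4, 5 and 6 the blocked test called 10, 3, 12 and 21 genes, and the unblocked test 0. TiO2 replicate 1 stood apart, with a median of 39841 UMIs per Krt8/Krt18-high cell against 17066.5 in replicate 2 and 42.63% of its cells unnamed. Genes named in advance had an adjusted p of 1, with Gdf15 at 254.1 ± 77.6 CPM against 368.8 ± 14.1 in control, Hmox1 at 39.8 ± 18 against 59.9 ± 11.9 and Mt2 at 111.3 ± 128.2 against 91.1 ± 86.4. Mt1 (1034.7 ± 1153.8), Cxcl2 (368.1 ± 400.7), Ddit3 (341.5 ± 371.1) and Cdkn1a (591.6 ± 180.3) were the others, and Il1b (3.7), Tnf (2.2) and Nlrp3 (2.1) lay near the floor.

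In macrophage-like cells immediate early genes fell with TiO2, 26 of 28 lower (median log2 -0.3, camera adjusted p = 1.08e-10, adjusted p = 0.29 with an estimated correlation), a call that held without each library. Klf2 (-0.94 ± 0.27 SE) and the transcription factors Fos (-0.94 ± 0.52) and Egr1 (-0.6 ± 0.53) are examples. Hypoxia response genes fell, 16 of 19 lower (-0.24, adjusted p = 7.1e-06, adjusted p = 0.191 with an estimated correlation). The lipid droplet gene Hilpda stood at -0.67 ± 0.36. S phase genes rose, 35 of 41 higher (0.15, adjusted p = 3.93e-07, adjusted p = 0.426 with an estimated correlation), with Dtl, a ubiquitin ligase subunit, at 0.39 ± 0.2. So did G2 and M phase genes, 42 of 53 higher (0.08, adjusted p = 7.94e-05, adjusted p = 0.501 with an estimated correlation), with Mki67 at 0.27 ± 0.16. With the block hypoxia and S phase held without each library, and G2 and M was lost only without control replicate 1. Unblocked, these lists were lost without control replicate 2, and the phase lists also without TiO2 replicate 1. In that library 36% of these cells carried markers of both classes against 13.4% in replicate 2. Median UMIs were 4798 against 34187.5. Cholesterol genes rose, 20 of 23 higher (0.15, adjusted p = 0.00012, adjusted p = 0.29 with an estimated correlation). Neither fit called them without TiO2 replicate 2.

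Unfolded protein response genes rose with TiO2 (0.0169, adjusted p = 0.29 with an estimated correlation), with the chaperone Hsp90b1 at 0.24 ± 0.14. The call was lost unblocked without any 1 control or TiO2 library. Falls of p53 targets (0.0466, adjusted p = 0.814 with an estimated correlation) and glycolysis genes (0.0466, adjusted p = 0.764 with an estimated correlation) were the weakest. The p53 call was lost unblocked without control replicate 1, TiO2 replicate 2 or either V2O5 library. Both calls were lost without cells with markers of both classes (0.0687 for p53 targets, 0.0521 for glycolysis genes). Unblocked, the glycolysis call was lost without any 1 of the 8 libraries. The block added rises of scavenger receptor genes (adjusted p = 0.0882, blocked 0.0165) and mitochondrially encoded transcripts (0.0545, blocked 0.0456), both lost in the blocked fit (adjusted p = 0.681 with an estimated correlation). The mitochondrial call was lost without cells with markers of both classes (blocked 0.213). The 15 lists not called ranged from 0.0545 to 0.987. Blocked DESeq2 called some genes, but unblocked DESeq2, limma-voom and adjustment over the list alone called 0. None passed in edgeR (0 of 12502, 49 at an unadjusted p under 0.05) or its blocked test. The blocked count ran from 0 to 9 with 1 library left out. Genes named in advance had an adjusted p of 1: Gdf15 stood at 699.5 ± 165 CPM against 1092.4 ± 50 in control, Hmox1 at 851.8 ± 84.4 against 944.2 ± 156, Tnf at 120.2 ± 2.3 against 131.3 ± 33.2 and Il1b at 379.6 ± 262.5 against 489.1 ± 339.3. Mt1 (2650.3 ± 1700.2), Mt2 (516.3 ± 338.6), Cxcl2 (800 ± 232.3), Cdkn1a (291.1 ± 19.5), Ddit3 (140.3 ± 106.3) and Nlrp3 (55.6 ± 32.8) were the others.

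The comparison of GO with control addressed a carbon sheet material in place of an oxide. In Krt8/Krt18-high cells NF-kB cytokines and chemokines fell, 25 of 37 lower (median log2 -0.28, camera adjusted p = 6.28e-09, adjusted p = 0.667 with an estimated correlation). Examples are Ptgs2 at -1.87 ± 0.29 SE, the nitric oxide synthase Nos2 at -1.38 ± 0.35, the acute-phase gene Saa3 at -1.24 ± 0.27 and the chemokine Ccl3 at -1.34 ± 0.37. The list also fell in clusters 2, 4, 5 and 6 (3.1e-07, 1.14e-06, 1e-06 and 2.3e-10). Scavenger receptor and phagocytosis genes fell, 16 of 24 lower (-0.38, adjusted p = 0.000671, adjusted p = 0.667 with an estimated correlation), with the receptor Clec4d at -1.12 ± 0.38. Many members of both lists are far higher in macrophage-like cells. The median level of macrophage markers in Krt8/Krt18-high cells was 143.75 ± 26.66 CPM with GO and 252.5 ± 34.08 CPM in control (difference -108.75, exact permutation p = 0.33). Without genes far higher in macrophage-like cells neither list passed (0.319 for NF-kB, blocked 0.00892, and 0.643 for 8 scavenger receptor genes). Both were lost without control replicate 1 (0.722 and 0.23), the NF-kB list also without GO replicate 2 (0.232). With the block the NF-kB call held without each of the 8 libraries.

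Levels of mitochondrially encoded transcripts rose with GO, 10 of 13 higher (adjusted p = 4.68e-06, adjusted p = 0.667 with an estimated correlation), a call that held without each library. The median mitochondrial share of UMIs in these cells was 6.82 ± 0.52% with GO, 6.26 ± 0.37% with V2O5, 6.42 ± 1.63% with TiO2 and 5.72 ± 0.4% in control. Cholesterol genes rose, 21 of 23 higher (0.15, adjusted p = 0.0119, adjusted p = 0.667 with an estimated correlation), and so did S phase genes, 35 of 41 higher (0.1, adjusted p = 0.0119, adjusted p = 0.881 with an estimated correlation). Both were lost without control replicate 2 (0.904 and 0.675) and without GO replicate 1 (0.0616 and 0.513). Within clusters, cholesterol genes rose in cluster 5 alone of the 4 (0.0301) and S phase genes in cluster 4 alone (0.00179). Called lists numbered 5, with 12 and 11 without GO replicates 1 and 2 and 9 with the block. The block added falls of NRF2 (adjusted p = 0.0987, blocked 0.0323), inflammasome (0.125, blocked 0.037), interferon response (0.0557, blocked 0.0234) and lysosome genes (0.174, blocked 0.037), all lost in the blocked fit (adjusted p = 0.835 with an estimated correlation). Without genes far higher in macrophage-like cells the NRF2 (blocked 0.226) and inflammasome (blocked 0.719) calls were lost. The 18 lists not called ranged from 0.0557 to 0.961. Adjusted over the list alone, 2 genes passed, Ptgs2 and the phosphoprotein gene Spp1 (-0.87), which is high in macrophage-like cells. Over all 14743 genes edgeR called 0, with 242 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. It also called 0 with the block, which became 4 and 7 without V2O5 replicates 1 and 2 and 307 with only the 4 libraries compared. Within clusters 2, 4, 5 and 6 the blocked test called 44, 23, 16 and 50 genes (unblocked 0, 0, 0 and 3). There the malic enzyme Me1, which makes NADPH, fell in clusters 2, 5 and 6 (-0.93 ± 0.16, -1.22 ± 0.17 and -1.01 ± 0.14; adjusted p = 1.61e-05, 7.7e-05 and 3.31e-09; chromosome 9, 86581371 to 86695953). Genes named in advance had an adjusted p of 1, with Hmox1 at 37.3 ± 21.6 CPM against 59.9 ± 11.9 in control, Gdf15 at 275.1 ± 129.3 against 368.8 ± 14.1 and Mt2 at 96.7 ± 109.7 against 91.1 ± 86.4. Cxcl2 stood at 313 ± 310.6, with log2 differences of -0.47 and -0.55 within the replicate numbers (blocked adjusted p = 0.508). Mt1 (840.1 ± 893.3), Ddit3 (448 ± 529.7) and Cdkn1a (599.5 ± 254.5) were the others, and Il1b (1.9), Tnf (1.5) and Nlrp3 (1.8) lay near the floor.

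In macrophage-like cells scavenger receptor and phagocytosis genes rose with GO, 20 of 24 higher (median log2 0.31, camera adjusted p = 1.29e-06, adjusted p = 0.48 with an estimated correlation). Examples are the mannose receptor Mrc1 (1.63 ± 0.57 SE), the Fc receptor Fcgr3 (1.12 ± 0.61) and the scavenger receptor Marco (0.9 ± 0.45). Cells with markers of both classes made up 16% and 11.9% of this class with GO against 36.2% and 12.2% in control, and without them the list still passed (3.33e-06). The median level of macrophage markers was 12590.1 and 24995.7 CPM with GO against 10937.1 and 20786.3 CPM in control. Unfolded protein response genes rose, 20 of 21 higher (0.18, adjusted p = 3.98e-05, adjusted p = 0.176 with an estimated correlation), with the chaperones Calr (0.35 ± 0.16), Hsp90b1 (0.31 ± 0.14) and Manf (0.3 ± 0.13). Cholesterol genes rose, 21 of 23 higher (0.19, adjusted p = 2.69e-05, adjusted p = 0.286 with an estimated correlation), with the synthase Hmgcs1 at 0.57 ± 0.21. Both of these calls held without each of the 8 libraries. The scavenger receptor call held with the block but was lost unblocked without control replicate 1 or GO replicate 2. p53 targets fell, 21 of 25 lower (-0.14, adjusted p = 0.00452, adjusted p = 0.587 with an estimated correlation), with Cdkn1a at -0.48 ± 0.2. Hypoxia response genes fell, 16 of 19 lower (-0.18, adjusted p = 0.00859, adjusted p = 0.286 with an estimated correlation), with Hif1a, the oxygen-regulated factor, at -0.42 ± 0.15. The p53 call was lost unblocked without control replicate 1 or GO replicate 2, and hypoxia without control replicate 2 or GO replicate 1.

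Smaller list changes with GO in these cells were falls of immediate early genes (0.0176, adjusted p = 0.587 with an estimated correlation), NRF2 and antioxidant genes (27 of 30 lower, 0.024, adjusted p = 0.67 with an estimated correlation; superoxide dismutase Sod1 at -0.4 ± 0.19) and AhR and xenobiotic metabolism genes (0.0392, blocked 0.0904, adjusted p = 0.587 with an estimated correlation). A rise was called for lysosome and autophagy genes (0.0273, adjusted p = 0.587 with an estimated correlation). Unblocked, all 4 were lost without control replicate 1 or GO replicate 2, and lysosome also without cells with markers of both classes (0.0541). With the block NRF2 held without each library. The 14 lists not called ranged from 0.0581 to 0.967, with metallothionein genes and NF-kB genes both at 0.0581. Unblocked edgeR called 0 of 12502 genes, with 148 at an unadjusted p under 0.05. Unblocked DESeq2, limma-voom and adjustment over the list alone called 0. The blocked edgeR test called 1 gene, 1600015I10Rik, which was named after its value was seen. That count ran from 0 to 20 with 1 library left out and was 151 with only the 4 libraries compared. Genes named in advance had an adjusted p of 1, with Hmox1 at 857 ± 83.2 CPM against 944.2 ± 156 in control, Gdf15 at 873.2 ± 291.6 against 1092.4 ± 50, Tnf at 122.2 ± 7.1 against 131.3 ± 33.2 and Il1b at 404.7 ± 359.6 against 489.1 ± 339.3. Cdkn1a stood at 259.5 ± 28.7 against 362 ± 98.2. Cxcl2 stood at 645.9 ± 337.4 against 863.6 ± 391.1, with log2 differences of -0.37 and -0.53 within the replicate numbers (blocked adjusted p = 0.64). Mt1 (2655.5 ± 1582.1), Mt2 (522.9 ± 334.8), Ddit3 (177 ± 152.3) and Nlrp3 (51.2 ± 23.7) were the others.

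**Figure D3:**
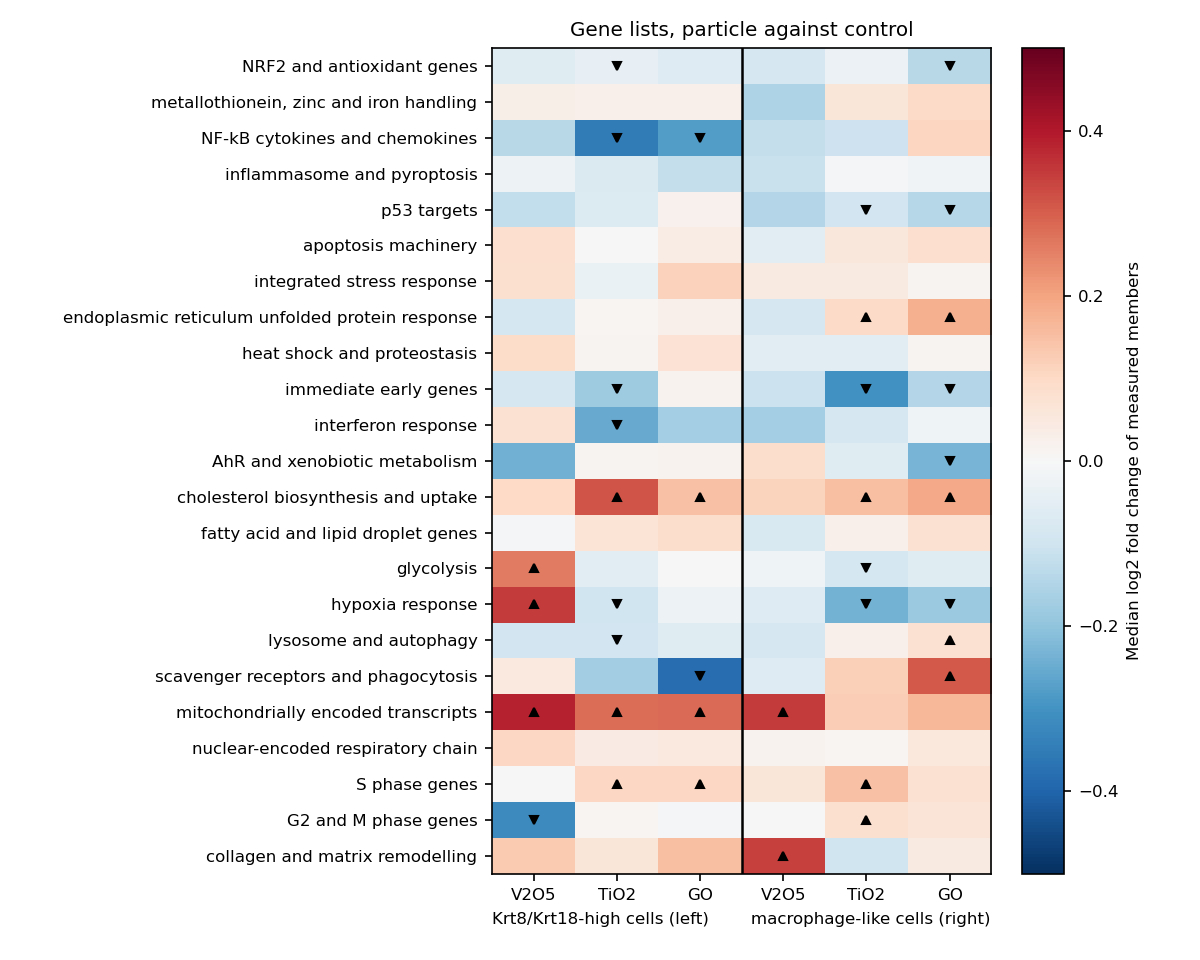
Median log2 fold change against control (colour) of each of the 23 lists (y axis) for each particle (x axis), in Krt8/Krt18-high cells (left 3 columns) and macrophage-like cells (right 3 columns); triangles mark lists called by camera at the preset correlation. Cholesterol genes are called up for TiO2 and GO in both classes and not for V2O5, and mitochondrially encoded transcripts are called up in 4 of the 6 columns.

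Direct comparisons between particles at 1 mass dose and time use no control library. In Krt8/Krt18-high cells genes of the hypoxia response were higher with V2O5 than with TiO2 (18 of 19, median log2 0.42, camera adjusted p = 1.34e-05, adjusted p = 0.808 with an estimated correlation) and than with GO (0.000757, adjusted p = 0.901 with an estimated correlation). Against TiO2, Ero1l, an oxidase of protein folding, stood at 0.79 ± 0.3 SE and the collagen hydroxylase P4ha2 at 0.46 ± 0.13. The same held in clusters 2, 4, 5 and 6 (0.00151, 2.81e-05, 2.2e-05 and 1.31e-05 against TiO2; 0.0017, 0.000252, 0.0205 and 0.00557 against GO). Glycolysis genes were higher than with TiO2 (3.17e-05, adjusted p = 0.808 with an estimated correlation) and GO (0.00214, adjusted p = 0.901 with an estimated correlation), with the enolase Eno1 (0.38 ± 0.12) and the aldolase Aldoa (0.3 ± 0.09) against GO. G2 and M phase genes were lower in the pooled set, 51 of 53 against TiO2 (6.74e-13) and 52 of 53 against GO (1.26e-08), but higher in cluster 5 (4.02e-06 and 1.01e-13) and lower in cluster 6 (3.25e-08 and 0.00557). The pooled calls were lost (adjusted p = 0.808 and adjusted p = 0.901 with an estimated correlation). Unblocked, hypoxia calls were lost without V2O5 replicate 1, TiO2 replicate 2 or GO replicate 2, and glycolysis against GO without V2O5 replicate 1. With the block these held, but G2 and M against GO was lost without V2O5 replicate 1.

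The edgeR test called 0 genes for V2O5 against TiO2 (649 at an unadjusted p under 0.05, 27 in DESeq2, 0 in limma-voom) and 0 against GO (922, 57 and 0). With the block it called 62 (34 up, 28 down) and 227 (114 up, 113 down). Against TiO2 the largest by rule were rises of the cornified envelope genes Sprr2e (2.54 ± 0.2, adjusted p = 0.00976) and Sprr2b (40.4 against 15.6 CPM, 0.0489), Stc1 (1.37, 0.00385), the monocyte chemokine Ccl7 (1.07, 0.0277) and Uchl3 (0.79, 0.048). The falls were of Hist3h2a (-1.33, 0.0349), Txnip (-1.32, 0.0321), Wfdc12 (-0.93, 0.048), Ablim1 (-0.92, 0.048) and H2-Q1 (-0.9, 0.0412). Against GO they were Sprr2e (3.32, 0.00272), Sprr1a (2, 0.0394), Sprr2b (1.93, 0.0144), Ccl7 (1.44, 0.00459) and Stc1 (1.31, 0.00272) upward. Downward they were Txnip (-1.43, 0.0144), Hist3h2a (-1.4, 0.0144), the matrix protein Thbs1 (-1.33, 0.016), Ablim1 (-1.13, 0.0144) and H2-Q1. Sprr2 genes lie as near-identical copies on chromosome 3, so their reads are hard to assign. With 1 library left out the count of 62 ran from 0 to 1845 and that of 227 from 0 to 2144, and with only the 4 libraries they were 2 and 69.

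Other lists called for V2O5 against TiO2 in this class were interferon response genes (0.000241) and heat shock genes (0.0316), both higher, and cholesterol genes, 22 of 23 lower (0.00145), with 11 lists called without TiO2 replicate 2 in place of 6. All 6 calls were lost with an estimated correlation (smallest adjusted p = 0.808). The interferon call was lost without V2O5 replicate 1, and cholesterol unblocked without V2O5 replicate 2 or TiO2 replicate 1. The heat shock call was lost without 5 of the 8 libraries (0.0511 to 0.809). Against GO, NF-kB genes (0.0181) and interferon genes (0.0108, blocked 0.0604) were higher, p53 targets were lower with the block (0.046, adjusted p = 0.899 with an estimated correlation), and 10 lists were called without GO replicate 2 in place of 5. All 5 calls were lost with an estimated correlation (smallest adjusted p = 0.901). The unblocked NF-kB and interferon calls were lost without V2O5 replicate 1 or 1 of the GO libraries, NF-kB also without V2O5 replicate 2. For GO against TiO2, NF-kB genes (0.000765), cholesterol genes (0.000218) and scavenger receptor genes (0.00822) were lower (adjusted p = 0.987 with an estimated correlation for each). The block added rises of apoptosis machinery (0.0454) and immediate early genes (0.000279), both lost in the blocked fit (adjusted p = 0.713 with an estimated correlation). There were 10, 11 and 10 lists called without GO replicate 1, GO replicate 2 and TiO2 replicate 1 in place of 3. Unblocked, NF-kB was lost without GO replicate 2 or TiO2 replicate 1, and scavenger receptors without GO replicate 1 or TiO2 replicate 2. Cholesterol was lost without TiO2 replicate 1 but held with the block. Lists not called ranged from 0.133 to 0.986 against TiO2, 0.0567 to 0.919 against GO and 0.0608 to 0.968 for GO against TiO2. Adjusted over the list alone 1, 6 and 0 genes passed in the 3 comparisons, the 6 being Ptgs2, Nos2, Txnip, Pycard, Spp1 and Mmp12. GO against TiO2 gave 0 genes in edgeR with and without the block, DESeq2 and limma-voom, and 30 at an unadjusted p under 0.05.

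In macrophage-like cells 10 lists were called between V2O5 and GO at the preset correlation. Scavenger receptor genes were lower with V2O5 in 22 of 24 (median log2 -0.39, camera adjusted p = 0.000205, adjusted p = 0.409 with an estimated correlation), with Clec4e at -1.05 ± 0.3 SE and Tlr2 at -0.9 ± 0.31. Unfolded protein response genes were lower in 20 of 21 (-0.26, 0.000417, adjusted p = 0.289 with an estimated correlation), the only list that also passed fry (0.0413), which it did not with the block (0.0858). In the other 11 comparisons fry called 0 lists in either fit. Lysosome and autophagy genes (0.00117), NF-kB genes (0.00337), metallothionein, zinc and iron genes (0.00678) and interferon genes (0.0447, blocked 0.0573) were lower. Mitochondrially encoded transcripts (0.000205), collagen and matrix genes (0.0013), AhR genes (0.0254) and hypoxia genes (0.0271) were higher. All 10 calls were lost with an estimated correlation (smallest adjusted p = 0.289). The unblocked edgeR test called 0 genes, with 714 at an unadjusted p under 0.05, 17 in DESeq2 and 1 in limma-voom, and the blocked test called 102 (40 up, 62 down). By rule these named Mmp12 (1.88, 0.00135), the growth inhibitor Ddit4 (0.96, 0.0195), the cytokine Il1b (0.91, 0.026), Odc1 (0.0264) and Wdr70 (0.77, 0.029), which were higher with V2O5. Lower were Cxcl10 (-1.42, 0.00445), Ccrl2 (-1.36, 0.026), Fabp3 (-1.31, 0.0102), the chemokine Ccl5 (-1.14, 0.0498) and Apoe (-1.13, 0.0377). The count of 102 ran from 8 to 400 with 1 library left out. It became 296 without cells with markers of both classes, and 20 with only the 4 libraries. Without V2O5 replicate 2, 8 of the 10 unblocked list calls were lost, all but the mitochondrial and AhR calls. Without V2O5 replicate 1 these 2 and hypoxia were lost. Without GO replicate 1 the metallothionein, NF-kB, interferon and hypoxia calls were lost, and without GO replicate 2 the scavenger receptor, collagen and AhR calls. The AhR call was also lost without cells with markers of both classes (0.0997).

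V2O5 against TiO2 in macrophage-like cells gave 7 lists. Mitochondrially encoded transcripts (2.25e-05), collagen and matrix genes (3.85e-05), hypoxia genes (0.00257) and immediate early genes (0.0316) were higher with V2O5, and unfolded protein response (0.0274), S phase (0.0316) and G2 and M phase genes (0.0316) were lower. The smallest value among them was adjusted p = 0.37 with an estimated correlation. Without cells that carried markers of both classes the unfolded protein response (0.0971), S phase (0.0742) and G2 and M phase (0.451) calls were lost. The block added lower metallothionein (0.0225), lysosome (0.015) and scavenger receptor genes (0.015), all lost in the blocked fit (smallest adjusted p = 0.543 with an estimated correlation). Called lists numbered 12 and 2 without V2O5 replicates 1 and 2. The unblocked hypoxia, collagen, unfolded protein response, S phase and G2 and M phase calls were lost without V2O5 replicate 2, immediate early without replicate 1. Without TiO2 replicate 1 both phase calls were lost, and without replicate 2 the hypoxia, unfolded protein response and immediate early calls. The edgeR test called 0 genes (466 at an unadjusted p under 0.05, 8 in DESeq2, 0 in limma-voom) and 6 with the block, among them Mmp12 (1.52, 0.00382), higher, and Clec4e (0.0247), lower. The 6 ran from 1 to 113 with 1 library left out, and became 104 without cells with markers of both classes and 154 with only the 4 libraries.

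GO against TiO2 in macrophage-like cells gave higher scavenger receptor genes, 23 of 24 (median log2 0.22, camera adjusted p = 0.000459), immediate early genes (0.00826), NF-kB genes (0.0109), lysosome genes (0.0144), interferon genes (0.0268) and unfolded protein response genes (0.0325). S phase (0.0112) and NRF2 genes (0.0144) were lower, with adjusted p from 0.581 to 0.687 with an estimated correlation. The block added higher fatty acid genes (0.0366) and lower G2 and M phase genes (0.0175), both lost in the blocked fit (adjusted p = 0.643 with an estimated correlation). Each unblocked call was lost without at least 1 GO and 1 TiO2 library. The edgeR test called 0 genes (61 at an unadjusted p under 0.05, 2 in blocked DESeq2, 0 in unblocked DESeq2 and limma-voom), 0 with the block and 12 with the block in only the 4 libraries, and the blocked count was 1 without control replicate 1 or 2. Lists not called ranged from 0.0743 to 0.919 for V2O5 against TiO2, 0.118 to 0.823 for V2O5 against GO and 0.0518 to 0.952 for GO against TiO2. Adjusted over the list alone 4, 5 and 0 genes passed, among them Csf3 and Ier3 against TiO2 and Ier3 and the lipid receptor Trem2 (-0.73) against GO.

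Whether the 2 classes responded differently was tested as an interaction. For V2O5, TiO2 and GO edgeR called 0 genes without the block, with 462, 91 and 374 at an unadjusted p under 0.05 and 0, 0 and 5 in DESeq2. The blocked test called 4 genes for V2O5, all with a lower fold change in macrophage-like than in Krt8/Krt18-high cells: the fatty acid carrier Fabp5, the lipoprotein Apoe, the inflammasome adaptor Pycard and the antiviral gene Rsad2. In self-tests the blocked interaction test called 26 unchanged genes. The blocked test called 0 for TiO2 and 0 for GO (lowest adjusted p = 0.0522). The GO count became 85 without control replicate 2, 89 and 98 without V2O5 replicates 1 and 2, 13 without cells with markers of both classes and 593 with only the 4 libraries. The TiO2 count ran from 0 to 3 with 1 library left out. The V2O5 count of 4 became 0 without control replicate 1, 6 without control replicate 2, 290 and 266 without V2O5 replicates 1 and 2 and 0 without any GO or TiO2 library. It became 2 with a stricter cell filter and 33 without cells with markers of both classes.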

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

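The interaction and the replicate block were fixed from the start, while the blocked counts with 1 library left out were chosen after the results were seen. The 4 genes were picked by the class interaction with the replicate block where the unblocked interaction had called 0 genes. The fold change with V2O5 was lower in macrophage-like than in Krt8/Krt18-high cells for 4 genes in the blocked edgeR interaction: the fatty acid carrier Fabp5 (log2 difference -0.83, adjusted p = 0.0357), the lipoprotein Apoe (-1.91, 0.0345), the inflammasome adaptor Pycard (-1.38, 0.0345) and the antiviral gene Rsad2 (-1.83, 0.0345). In Krt8/Krt18-high cells Fabp5 stood at 95.4 and 77.3 CPM in control and at 138.29 and 133.37 with V2O5, and in macrophage-like cells at 1806 and 2296 in control and 1715 and 1914 with V2O5. Pycard stood at 6.36 and 4.92 CPM in control and 11.4 and 7.42 with V2O5 in the first class, against 270.5 and 528 in control and 166.7 and 335.8 with V2O5 in the second. All 4 genes were far higher in macrophage-like cells, and how much of their level in the other class was free or carried-over RNA was not tested. The interaction count of 4 was 0 without control replicate 1 or any 1 of the GO and TiO2 libraries, 6 without control replicate 2, and 290 and 266 without V2O5 replicates 1 and 2.

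In TiO2 replicate 1, 42.63% of cells fell in unnamed clusters, against 3.48% in TiO2 replicate 2 and 9.69% and 8.22% in the controls. Most were the 1849 cells of cluster 7, a shallow cluster with a median of 2502 UMIs, led by AY036118 and Cxcl15, and the 35 cells of cluster 8, led by the class II antigen chain Cd74, came from this library alone.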

How the results depend on the processing

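The removal of cells with the highest doublet scores or with markers of both classes, and each setting combined with the replicate block, were tests chosen after the results were seen. Of 740 counts and shares recomputed, 570 stayed within 1.5 times their value or their spread and 170 moved. Many of the 570 were counts that stayed at 0, and the TiO2 share difference of 1.66 points was -5.49 without TiO2 replicate 1. For those that moved the cause was not tested unless named. RLE size factors, doublet calls kept and a shallow cluster added to the Krt8/Krt18-high set moved none of them. Of 2474 values for named genes 2280 kept their side of the threshold, 71 passed it and 123 moved. Of 714 values for lists 543 kept it, 112 lost it, 48 gained it and 11 moved. Depth bears most on low-count genes, and V2O5 replicate 1 had the smallest UMI sum in both classes.

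With the replicate block edgeR called 9, 62 and 227 genes in Krt8/Krt18-high cells for V2O5 against control, TiO2 and GO, in place of 0 each. In macrophage-like cells it called 12, 6 and 102 for the same 3 comparisons and 1 for GO against control, in place of 0. The block gave 4 genes for the V2O5 interaction between classes in place of 0, and took called lists from 5 to 9 for GO against control and from 3 to 5 for GO against TiO2 in Krt8/Krt18-high cells, and from 2 to 6 for V2O5 against control in macrophage-like cells. With an estimated correlation in camera the number of called lists was 0 in each of the 12 comparisons.

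DESeq2 without the block called 10, 27 and 57 genes for V2O5 against control, TiO2 and GO in Krt8/Krt18-high cells, 1 for TiO2 and 1 for GO against control, 7, 8 and 17 for V2O5 against control, TiO2 and GO in macrophage-like cells, and 5 for the GO interaction. With the block DESeq2 called 680, 647 and 1061 in the first of these classes and 56, 101 and 197 in the second for the 3 V2O5 comparisons, 56 and 24 for GO and 5 and 11 for TiO2 against control in the 2 classes, and 36 and 14 for the V2O5 and GO interactions. limma-voom with the block called 31 for V2O5 against control in Krt8/Krt18-high cells, and in macrophage-like cells 0 for GO against control and 64 for V2O5 against GO, where it called 1 without the block. With no low-count filter and the block, V2O5 against control, TiO2 and GO gave 284, 330 and 694 genes in Krt8/Krt18-high cells and 114, 178 and 349 in macrophage-like cells, and GO against control gave 20 there. Without the block the missing filter left Krt8/Krt18-high counts at 0 but gave 101, 19 and 47 genes in macrophage-like cells for V2O5, TiO2 and GO against control, 120 and 211 for V2O5 against TiO2 and GO, and 17 for GO against TiO2.

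With only the 4 libraries compared, which leaves fewer samples for the spread, the blocked counts in Krt8/Krt18-high cells were 0, 2 and 69 for V2O5 against control, TiO2 and GO, those in macrophage-like cells 0, 154 and 20, those for GO against control 307 and 151 in the 2 classes, and those for the V2O5, TiO2 and GO interactions 0, 3 and 593. Against a fold of 1.2 in glmTreat the blocked counts were 8 and 41 for V2O5 against TiO2 and GO in Krt8/Krt18-high cells, 4 and 19 for V2O5 against control and GO in macrophage-like cells, and 0 for the V2O5 interaction. Profiles thinned to the smallest library gave blocked counts of 35 for V2O5 against control in Krt8/Krt18-high cells, of 19, 23 and 0 in macrophage-like cells for V2O5 against control, V2O5 against TiO2 and GO against control, and 1 unblocked gene for V2O5 against GO. Without genes far higher in the other class the blocked count for V2O5 against control in Krt8/Krt18-high cells was 38. All cells summed gave 7 blocked genes for V2O5 and 0 for GO against control, set beside 12 and 1 in macrophage-like cells.

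Cell filters and classes moved results as follows, with the block unless stated. No barcode filter gave 21 for V2O5 against TiO2 in Krt8/Krt18-high cells, 60, 83 and 266 for V2O5 against control, TiO2 and GO in macrophage-like cells, 1 unblocked gene in the last, 38 for the V2O5 interaction, and a V2O5 difference in macrophage-like share of -4 points. The stricter filter gave 1 unblocked gene for V2O5 against GO in macrophage-like cells and 2 for the interaction. Each library clustered by itself gave 104 for V2O5 against TiO2 in Krt8/Krt18-high cells and a V2O5 share difference of -2.83 points. Without the highest doublet scores the macrophage-like counts were 43, 40 and 232 for V2O5 against control, TiO2 and GO, with 1 unblocked gene in the last, and 7 for the interaction. Without cells that carried markers of both classes they were 79, 104 and 296, with 1 unblocked gene each against TiO2 and GO, 8 for GO against control, 33 for the interaction, and 4 called lists for V2O5 against TiO2.

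Leaving out 1 library left every unblocked edgeR count of genes at 0. Of 76 list calls without the block 12 held without each library, and of 95 with the block 27 held. A lone library left in a group is assumed to vary like the other groups. Blocked counts then ran from 0 to 2314, 0 to 1845 and 0 to 2144 for V2O5 against control, TiO2 and GO in Krt8/Krt18-high cells, from 4 to 197, 1 to 113 and 8 to 400 in macrophage-like cells, from 0 to 7 and 0 to 20 for GO against control in the 2 classes and 0 to 9 for TiO2 against control in macrophage-like cells. For the V2O5, TiO2 and GO interactions they ran from 0 to 290, 0 to 3 and 0 to 98. Called lists in Krt8/Krt18-high cells ran from 4 to 9 for V2O5 against control, 6 to 12 for GO against control, 4 to 11 and 4 to 10 for V2O5 against TiO2 and GO, and 3 to 11 for GO against TiO2. In macrophage-like cells they ran from 1 to 8, 2 to 12 and 2 to 11 for V2O5 against control, TiO2 and GO.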

Other observations

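The tests of a shift of cells between clusters, the cluster shares, the tests of single clusters and the effect of the replicate number were chosen after the results were seen, as was the use of the blocked fit to read tests with a library left out. The make-up of the Krt8/Krt18-high set is given here by library. Cluster 3, led by the cornified envelope genes Sprr2e and Sprr2j-ps, the protease inhibitor Serpinb2 and the interferon-induced Gbp2, held 75.3% of these cells in V2O5 replicate 1, against 21.46% in control replicate 1, 44.67% in TiO2 replicate 1 and 41.32% in GO replicate 1. Cluster 2, led by Cxcl1 and Csf2, held 19.44% with V2O5 against 67.85%, 45.62% and 53.67% in the same order. In replicate 2 cluster 6, led by Mki67 and Top2a, held 15.83% with V2O5 against 33% in control, 33.78% with TiO2 and 34.79% with GO, and cluster 4, led by Krt7, held 72.01% against 43.85%, 38.7% and 34.55%, but in replicate 1 it held 3.71% against 6.77% in control. Cluster 6 was also the smaller with V2O5 in replicate 1 (0.6% against 2.23%). These shares were not tested, and V2O5 cells had lower UMI counts, on which cluster calls depend.

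More genes were called between the libraries of replicate 1 and of replicate 2 than between any treated group and control. Compared across the 4 groups, 5799 of 14743 genes (39.3%) differed in Krt8/Krt18-high cells and 2885 of 12502 (23.1%) in macrophage-like cells by edgeR. In the first class the cytokine Csf2 (log2 -4.98), the metallothioneins Mt2 (-3.01) and Mt1 (-2.69), the stress factors Atf3 (-2.55) and Ddit3 (-2.4) and the chemokines Cxcl2 (-2.54) and Cxcl1 (-2.36) were lower in replicate 2, and Krt7 (0.95) and Angpt1 (1.5) were higher. NF-kB genes (23 lists tested by camera, adjusted p = 3.23e-31, adjusted p = 0.232 with an estimated correlation) and immediate early genes (6.28e-21, adjusted p = 0.293 with an estimated correlation) were lower, and respiratory chain genes were higher in 34 of 34 (2.5e-05, adjusted p = 0.293 with an estimated correlation). In macrophage-like cells Csf2 (-5.71) was lower and Apoe (2.68) higher, and NRF2 genes (5.87e-15, adjusted p = 0.155 with an estimated correlation) and integrated stress response genes (1.83e-09) were lower. In each class 12 lists were called, and with an estimated correlation 0. The labels give the libraries of replicate 1 and those of replicate 2 different codes and do not say what these stand for, so separate experiments, culture protocols or sequencing dates were not told apart.

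TiO2 and GO shared more of their fold changes against control in Krt8/Krt18-high cells than simulated unchanged groups with the same 2 control libraries. Across 5604 genes the covariance of the blocked log2 fold changes was 0.0162, against 0.0099 (SD 0.0003) in 10 simulations of unchanged groups, and 80.1% of genes had the same sign in both, against 66.6% simulated. The covariance was 0.0084 for V2O5 and GO (simulated 0.0099, SD 0.0004) and 0.009 for V2O5 and TiO2 (0.0098, SD 0.0004). In macrophage-like cells (4975 genes) it was 0.0165 (0.0142, SD 0.0014) for TiO2 and GO, under 2 SD apart, 0.0069 (0.014, SD 0.0009) for V2O5 and GO and 0.0093 (0.0138, SD 0.0014) for V2O5 and TiO2. Pairs with V2O5 thus lay below the simulated value, so that value is an uncertain baseline for TiO2 and GO too. Genes are not independent replicates, 2 control libraries cannot be split between comparisons, and 0 genes were called for both particles.

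Cholesterol genes were higher with TiO2 in Krt8/Krt18-high cells. The call held without the outlying TiO2 replicate 1 (camera adjusted p = 0.00135, blocked 3.09e-14), which argues against that library as the whole source. V2O5 against TiO2 contrasts no control library, though these libraries share the fit, and there the list was higher with TiO2 (0.00145, blocked 5.85e-06). This argues against low values in the control libraries alone. The call was lost with an estimated correlation, and without V2O5 replicate 2 or TiO2 replicate 1 unless blocked. The list was called up within 3 of the 4 clusters tested with the block, which argues against a shift between these, but cluster 3 was not tested. A response of sterol synthesis to TiO2 is a hypothesis consistent with these tests, found and tested on the same data and not called with an estimated correlation (0.261), and shared library effects stay open.

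NF-kB genes were lower with GO in Krt8/Krt18-high cells. They were called down within 4 of 4 clusters with the block, which argues against a shift of cells between these as the whole source. Cluster 3 was not tested, and it held 41.32% of these cells in GO replicate 1 against 21.46% in control replicate 1. Cluster 2 was led by Cxcl1 and Csf2, members of this list, so the clusters partly rested on the genes tested. A shift into cluster 3 therefore stays open. The pooled call was lost (camera adjusted p = 0.667 with an estimated correlation). Less RNA from macrophage-like cells with GO may account for the pattern: without genes far higher in those cells the list was not called (adjusted p = 0.319, median macrophage marker level 143.75 CPM with GO and 252.5 CPM in control), although the blocked test still called it (0.00892). With the block the call held without either control library (highest adjusted p = 0.000132), which argues against a single control library, while the unblocked value without control replicate 1 (0.722) also held the lower NF-kB level of replicate 2. An effect of GO on these genes was not told apart from less macrophage RNA.

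G2 and M phase genes were lower with V2O5 in Krt8/Krt18-high cells. The call held without either V2O5 library (highest adjusted p = 1.92e-06, blocked 0.0256), which argues against a single library, although the pooled call was lost (adjusted p = 0.889 with an estimated correlation). In 3 of 4 clusters the median lay nearer to 0 than 0.5 times the pooled median, so a lower share of cycling cluster 6 cells (15.83% against 33% in replicate 2) may carry much of the pooled change. A lower share of cycling cells and a change in how V2O5 cells were clustered at their lower depth both remain open, and no test here separated them.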
